A study of Homo sapiens with 12 samples.

How the data were processed

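Rh30 cells were treated for 6 h in 4 groups of 3 libraries each, called biological triplicates in the series design text. Total RNA was isolated with a peqGOLD kit, libraries were prepared with a TruSeq RNA kit and sequenced on a HiSeq4000, per the submitters' protocols. Reads were aligned with STAR 2.5 and tested with DESeq2 (version not given), per the submitters' processing notes, which name the builds GRCh37 and hg19. The counting program, its strand setting, the gene annotation and the treatment of reads that map to several places are not given in the sources used here.

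The deposited tables hold 38580 genes for each of 3 treatments against control. The signal values, mean normalized counts over all 12 libraries, were divided by size factors and averaged by the authors in DESeq2, per the file headers. The log2 fold changes and their standard errors were computed by the authors in DESeq2, per the file headers. The score values, Wald statistics, were deposited by the authors and equal the log2 fold change divided by its standard error. The p-values and the adjusted p-values were computed by the authors in DESeq2 with its independent filter, which left 23620, 13897 and 23620 genes for JQ1, BYL719 and the combination. The means were identical across the 3 tables, so 1 fit of 12 libraries was assumed. Values per library were not used here, so replicate agreement, batch and removal of single libraries were not examined. The design fixed before the data were examined allowed for counts, and its branch for fold changes alone was used.

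For treatments against control the authors' adjusted p under 0.05 was used. Differences between treatments were taken as differences of log2 fold changes, divided by the root of the summed squared standard errors, with normal p-values adjusted by the Benjamini-Hochberg method. This ignores the shared control libraries. As an alternative chosen after the data were seen, group levels were derived from the mean and the 3 fold changes, and the dispersion and the shared control variance were derived per gene from the standard errors. Median ratios of predicted to deposited standard error were 1.0003 for JQ1 and 1.0023 for BYL719. The shared part made up 50.0% of the variance at the median.

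The 23 gene lists and the comparisons were written down before the data were examined. Some lists share members, so their tests are not independent. The FOXO targets share IRS2, INSR, ERBB3 and IGF1R with the PI3K pathway and receptor genes. They were tested with cameraPR of limma on the Wald statistics with a preset correlation of 0.01, and again with 0.05, on ranks, with genes of a mean of at least 10 as background and with protein-coding genes as background. For differences the statistic with the per-gene error was used. Lists with fewer than 3 tested members were left out of this test, which concerned the epithelial markers in each comparison and the blood cell markers for BYL719, for the combination against BYL719 and for the interaction, and none of the 13 mitochondrially encoded genes was in the tables. List counts adjusted over the list alone used the Benjamini-Hochberg method on the members.

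Named genes were the 10 largest changes each way with a mean of at least 100 (5 each way for differences), key genes fixed beforehand and up to 4 members per list. Further genes, among them MDM2, MSMO1, SLC7A11, HSPA8, HSPA5, DNAJB1, RPS3, H3-3B, SNORA71A, WNT9A, ULK1, SLFN5, MYF5, SERTAD1, BAX and BAK1, were chosen after their values were seen, as were the families of heat shock, ribosomal protein, histone and small RNA genes. Scaling to total counts replaced the size factors by the derived total of each group, and the protein-coding alternative used GENCODE 29 gene types. Both were chosen after the data were seen.

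The difference test was tested on simulated data. With a log2 change of 1.00 in 200 of 13897 genes, 85.0% were found for the combination against JQ1 (90.5% with the per-gene error) and 72.0% for the interaction (85.5%). The reported test of the combination against JQ1 ran on 23620 genes, with means from 2.11 normalized counts. Its recovery was not simulated over all of its genes, so the 85.0% and 90.5% may be too high for it. Among unchanged genes of the simulation with a log2 change of 0.5, 0.52% had a p-value under 0.05 for the combination against JQ1, and 4.93% with the per-gene error. Counts were drawn with the derived dispersion of each gene, and the errors were computed from that same dispersion. Uncertainty in the dispersion is thus left out of all these rates. Of 500 simulated lists of 20 genes cameraPR gave an unadjusted p under 0.05 for 4.8% with no shift. It did so for 53.8% with a shift of 0.5 standard deviations and 99.2% with a shift of 1. With the correlation of 0.05 the shares were 0.6%, 30% and 96.4%. Members of the simulated lists were drawn independently, so these rates do not hold for lists of genes that change together. They are also not those of an adjusted p, by which the lists were called.

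Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Genomic coordinates were not used, because the tables and the reference differ in build.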

Results

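RNA was sequenced from Rh30 cells, an established line of alveolar rhabdomyosarcoma, a childhood soft tissue tumour with features of skeletal muscle. The line carries the PAX3-FOXO1 fusion gene. Cells were treated for 6 h with solvent, with 1 µM JQ1, with 3 µM BYL719 or with both compounds. JQ1 displaces BET bromodomain proteins from acetylated chromatin, and BYL719 (alpelisib) inhibits the alpha isoform of phosphoinositide 3-kinase (PI3K). Each of the 4 groups held 3 libraries, which the series design text calls biological triplicates, so p-values measure the spread between these 12 cultures. The values were taken from 3 tables of the authors, each comparing 1 treatment with the same 3 control libraries over 38580 genes. The tables gave 1 mean normalized read count per gene over the 12 libraries and no value per library, so the number of libraries that show a direction is unknown. Size factors read from the steps between the lowest means ran from 0.91 to 1.2, a ratio of 1.31 between the libraries. Among 12266 genes with a mean of at least 100 normalized counts, the root of the dispersion derived from the authors' standard errors had a median of 8.82%. It stands for a within-group coefficient of variation without counting noise, which was not measured on the libraries. The median standard error (SE) of a log2 fold change among these genes was 0.112 with JQ1, 0.111 with BYL719 and 0.112 with the combination. The words rose and fell denote an adjusted p under 0.05, relative to control unless another group is named.

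The first comparison asked which genes responded to BET inhibition alone. After JQ1, TEX14, which encodes a protein of germ cell intercellular bridges, rose 18.8-fold in the authors' deposited table (log2 4.23, SE 0.183, adjusted p = 7.22e-115). HEXIM1, an inhibitor of the elongation kinase complex P-TEFb and a common marker of BET inhibitor exposure, rose 8.35-fold in the authors' deposited table (95% interval 6.80 to 10.2). The stress-responsive gene SESN3 rose 13.8-fold and SMIM14 rose 16.8-fold in the authors' deposited table. The largest falls among genes with a mean of at least 100 were those of SH2D7 (log2 -3.82, SE 0.293) and the hyaluronan synthase gene HAS2 (log2 -3.48, SE 0.179) in the authors' deposited table. FGF8, a growth factor gene, fell 7.38-fold, LIF, a cytokine gene, 5.88-fold and the myogenic regulator MYOG 2.84-fold in the authors' deposited table.

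The other genes among the 10 largest rises with JQ1 in the authors' deposited table were SLFN5, H2BC20P, YPEL1, DHRS2, SCARA5 and IER5L, with folds from 5.29 for IER5L to 6.90 for SLFN5. H2BC20P is a histone pseudogene whose reads can be shared with other histone genes, so its value is uncertain. The other genes among the 10 largest falls in the authors' deposited table were LINC01915, FUT3, CHDH, DCLRE1A, LINC00840 and KANK1, between log2 -3.20 for LINC01915 and -2.54 for KANK1. The antisense or overlapping origin of reads at long non-coding genes such as LINC01915 and LINC00840 is open, since the strand setting of the counting is not given in the sources used here.

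Among 16 genes tested from the list of cyclin-dependent kinase (CDK) inhibitors and p53 targets, 15 rose with JQ1 and 1 fell, and the counts were 15 and 1 when adjusted over the list alone. CDKN2B rose 4.70-fold, CDKN1A (p21) 3.84-fold and SESN2 2.93-fold in the authors' deposited table, while MDM2, the gene of the p53 ubiquitin ligase, fell 1.54-fold. Of 22 FOXO target genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 change of 0.73. Among them KLHL24 rose 2.72-fold and CITED2 2.22-fold in the authors' deposited table. Of 10 genes known to rise with BET inhibitors, 9 rose and 0 fell (9 and 0 adjusted over the list alone), including HEXIM1. The uncalled member was H2BC11, at log2 0.19 (adjusted p = 0.255) in the authors' deposited table. Of 17 genes of glycolysis and glucose uptake, 11 rose and 0 fell (12 and 0 adjusted over the list alone), led by the glucose transporter gene SLC2A3 at 1.71-fold in the authors' deposited table. Of 20 genes of cholesterol synthesis and uptake, 10 rose and 1 fell (10 and 1 adjusted over the list alone). STARD4, a sterol carrier gene, rose 1.70-fold and the isomerase gene IDI1 1.64-fold in the authors' deposited table, while the sterol oxidase gene MSMO1 fell 1.33-fold. Of 20 genes of the ATF4 amino acid stress response, 9 rose and 2 fell (10 and 2 adjusted over the list alone). DDIT4, an inhibitor of mTORC1 signalling, rose 4.37-fold and the transcription factor gene ATF3 2.78-fold in the authors' deposited table. In the same list the pseudokinase gene TRIB3 fell 4.11-fold and the cystine transporter gene SLC7A11 fell 1.89-fold in the authors' deposited table. When scaled to total counts, these 6 lists, in the order given, had 14, 14, 6, 8, 8 and 7 rising members. The falling members were then 1, 0, 0, 0, 1 and 3.

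These 6 lists stood above the other genes in the cameraPR test of limma, with adjusted p from 3.55e-18 for CDK inhibitors and p53 targets to 0.00555 for cholesterol synthesis. A correlation between genes could not be estimated without values per library, so each list was tested again with a preset correlation of 0.05 in place of 0.01, and all 6 calls with JQ1 held. No list was called below the other genes with JQ1. MYC showed a log2 change of 0.04 (SE 0.0957, adjusted p = 0.802) in the authors' deposited table. Of 24 genes of the MYC list, 5 rose and 8 fell (5 and 8 adjusted over the list alone). When each group was scaled to its total count, 2 rose and 10 fell, and the median of 0.03 became -0.07. Of 11 BET proteins and partners, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with BRD2 up 2.58-fold in the authors' deposited table. Of 23 genes linked to PAX3-FOXO1 or to fusion-positive tumours, 4 rose and 7 fell (4 and 7 adjusted over the list alone), among them SOX8, which rose 1.70-fold, and OLIG2, which fell 1.72-fold in the authors' deposited table. Of 22 G1/S and replication genes, 6 rose and 9 fell (6 and 9 adjusted over the list alone), and of 18 G2/M genes 1 rose and 6 fell (1 and 7 adjusted over the list alone). GINS1, a replication factor gene, fell 1.77-fold and the mitotic kinase gene AURKA 1.77-fold in the authors' deposited table. The immediate early and ERK feedback list split evenly, with 7 of 21 rising and 7 falling (8 and 7 adjusted over the list alone).

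In all, 7424 of 23620 genes tested passed an adjusted p of 0.05 with JQ1 in the authors' deposited table, of which 3612 rose and 3812 fell. Of these, 1813 had an absolute log2 fold change of at least 1. Scaled to total counts in place of the authors' size factors, 2670 rose and 4935 fell, because that scaling lowers each log2 change by 0.102 with JQ1, 0.0129 with BYL719 and 0.219 with the combination. With the 20 most abundant genes left out of the totals, these shifts were 0.0816 with JQ1, -0.0171 with BYL719 and 0.0924 with the combination, so most of the combination's shift rests on 20 genes. Changes smaller than these shifts have a direction that depends on the scaling.

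**Figure D1:**
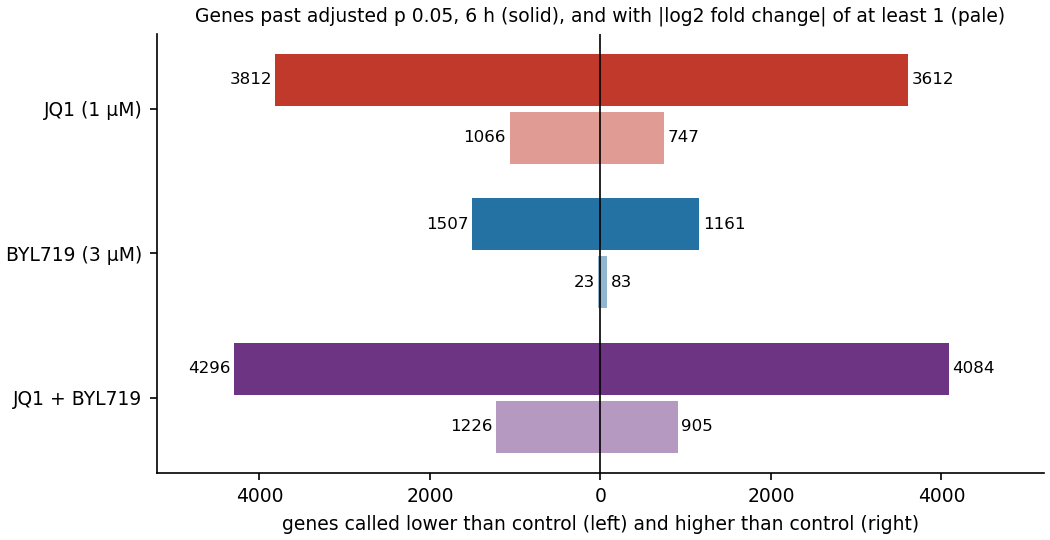
Numbers of genes past an adjusted p of 0.05 after 6 h in the authors' deposited tables, lower than control to the left and higher to the right of 0, for JQ1, BYL719 and the combination. Solid bars count all such genes (3812 and 3612 with JQ1, 1507 and 1161 with BYL719, 4296 and 4084 with the combination) and pale bars those with an absolute log2 fold change of at least 1; scaled to total counts, the solid bars would hold 4935 and 2670 genes with JQ1, 1690 and 1078 with BYL719, and 6765 and 2201 with the combination.

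The comparison of BYL719 with control asked which genes responded to PI3K alpha inhibition alone. BMF, which encodes a pro-apoptotic BH3-only protein of the BCL2 family, rose 5.93-fold in the authors' deposited table (log2 2.57, SE 0.229, adjusted p = 6.15e-26). The FOXO targets KLHL24, CCNG2 and FBXO32, of which the last encodes a ubiquitin ligase of muscle atrophy, rose 4.84-fold, 4.17-fold and 3.58-fold in the authors' deposited table. SMIM14 rose 6.69-fold (log2 2.74, SE 0.263) and the glucose transporter gene SLC2A12 5.65-fold in the authors' deposited table. Falls were smaller: BIRC3, an inhibitor of apoptosis gene, fell 4.13-fold (log2 -2.05, SE 0.254), the receptor tyrosine kinase feedback gene SPRY4 2.89-fold and the ERK phosphatase gene DUSP5 2.51-fold in the authors' deposited table. The abundant chaperone gene HSPA8 fell 2.24-fold (log2 -1.16, SE 0.144) in the authors' deposited table.

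The rest of the 10 largest rises with BYL719 in the authors' deposited table were ABTB1, BACH2, YPEL1 and CREBRF, from 3.26-fold for CREBRF to 4.04-fold for ABTB1. The rest of the 10 largest falls in the authors' deposited table were METTL7B, SEMA7A, TRAF1, FOSL1 and the pseudogenes HSPA8P9 and HSPA8P5, from 2.26-fold for HSPA8P5 to 2.63-fold for METTL7B. The values of both pseudogenes are uncertain, since their sequence is that of HSPA8 and reads can be shared between them.

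FOXO targets rose together: 16 of 21 rose and 0 fell (17 and 1 adjusted over the list alone), with a median log2 change of 0.68 and a cameraPR adjusted p of 1.80e-20. They included PIK3IP1, a negative regulator of PI3K (3.36-fold in the authors' deposited table), and the receptor genes IGF1R (1.72-fold) and INSR (1.63-fold). Cholesterol genes fell: 8 of 19 fell and 0 rose (10 and 0 adjusted over the list alone), with MSMO1 down 1.68-fold and the synthase gene HMGCS1 1.58-fold in the authors' deposited table (cameraPR adjusted p = 1.11e-06). Of 24 genes of the MYC list, 14 fell and 1 rose (14 and 1 adjusted over the list alone), with a cameraPR adjusted p of 1.11e-06. RRS1 and NOP56, genes of ribosome biogenesis, fell 1.51-fold and 1.46-fold and the iron uptake gene TFRC 1.44-fold in the authors' deposited table, whereas MYCN rose 1.35-fold and MYC stood at log2 0.19 (adjusted p = 0.145). Of 19 immediate early and ERK feedback genes, 10 fell and 3 rose (11 and 3 adjusted over the list alone), with FOSB among the risers at 3.11-fold in the authors' deposited table (cameraPR adjusted p = 4.30e-05). Of 22 G1/S genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), among them the phosphatase gene CDC25A (1.73-fold lower) and the cyclin genes CCND2 (1.58-fold lower) and CCND1 (1.42-fold lower) in the authors' deposited table. Of 16 CDK inhibitors and p53 targets, 7 rose and 2 fell (9 and 3 adjusted over the list alone), with TP53INP1 up 2.23-fold in the authors' deposited table. CDKN1A stood at log2 0.23 (adjusted p = 0.0505) in the authors' deposited table. Of 21 genes linked to PAX3-FOXO1, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with the chemokine receptor gene CXCR4 up 1.95-fold and the myogenic factor gene MYOD1 up 1.34-fold in the authors' deposited table.

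These lists, with the 3 that follow, were the 10 lists called with BYL719. Of 26 PI3K pathway and receptor genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone), and the list's cameraPR adjusted p of 0.0121 became an adjusted p of 0.0714 with the correlation of 0.05. Of 9 genes of fatty acid synthesis, 4 fell and 0 rose (4 and 0 adjusted over the list alone), with an adjusted p of 0.0292 that became an adjusted p of 0.0710 with that correlation. Of 4 anti-apoptotic BCL2 family genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.0217). The calls of the other 8 lists held with the correlation of 0.05, at adjusted p up to 0.0361. Among BET inhibitor-induced genes 0 of 9 rose and 0 fell (0 and 0 adjusted over the list alone), with HEXIM1 at log2 -0.05 (adjusted p = 0.878) in the authors' deposited table. Over all 13897 genes tested by DESeq2 with BYL719, 4235 had an unadjusted p under 0.05.

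In total, 2668 of 13897 genes passed an adjusted p of 0.05 with BYL719 in the authors' deposited table, of which 1161 rose and 1507 fell (1078 and 1690 when scaled to total counts). Of these, 106 changed by an absolute log2 of at least 1, of which 83 rose and 23 fell in the authors' deposited table. Fewer genes were tested than with JQ1 because the authors' independent filter removed genes with a mean under 42.9 normalized counts here and under 2.11 with JQ1.

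The comparison of the combination with control asked what both compounds did together. SMIM14 rose 54.4-fold in the authors' deposited table (log2 5.77, SE 0.257, adjusted p = 5.43e-108). SESN3 rose 16.0-fold, YPEL1 14.8-fold and KLHL24 9.15-fold in the authors' deposited table. Among pro-apoptotic genes BMF rose 4.79-fold (95% interval 3.51 to 6.54), BBC3 (PUMA) 2.82-fold, BCL2L11 (BIM) 2.62-fold and PMAIP1 (NOXA) 2.48-fold in the authors' deposited table. BCL2L1, the gene of the anti-apoptotic protein BCL-XL, fell 2.55-fold (log2 -1.35, SE 0.117), while MCL1 rose 1.33-fold in the authors' deposited table. The transcription factor gene FOSL1, a target of ERK signalling, fell 7.16-fold and the cyclin gene CCND2 2.09-fold in the authors' deposited table.

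The other large rises in the authors' deposited table were those of TEX14, SLC2A12, H2BC20P, HEXIM1, PAQR8 and SLFN5, from 6.88-fold for SLFN5 to 14.9-fold for TEX14. The largest falls in the authors' deposited table were those of SH2D7 (log2 -4.08, SE 0.311), LINC01679, HAS2, FGF8, LIF, FUT3, FOSL1, LINC00511, HAVCR2 and LINC02709 (log2 -2.76, SE 0.252).

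Across the BCL2 family the compounds differed by gene. In the authors' deposited tables BCL2L11 rose with JQ1 (2.14-fold), with BYL719 (1.51-fold) and with the combination, and BBC3 rose with each as well (1.81-fold with JQ1 and 2.17-fold with BYL719). BMF rose with BYL719 and the combination and stood at log2 0.45 (adjusted p = 0.151) with JQ1 in the authors' deposited tables. PMAIP1 rose with JQ1 (2.97-fold) and the combination and stood at log2 -0.73 (adjusted p = 0.0844) with BYL719 in the authors' deposited tables. BCL2L1 fell 2.40-fold with JQ1 and 1.24-fold with BYL719, and MCL1 rose 1.61-fold with JQ1 and fell 1.26-fold with BYL719 in the authors' deposited tables. BCL2 fell 1.65-fold with BYL719 and stood at log2 -0.39 (adjusted p = 0.202) with the combination in the authors' deposited tables. Of 11 pro-apoptotic members tested with the combination, 4 rose and 2 fell (4 and 3 adjusted over the list alone, 4 and 5 when scaled to total counts), the 2 that fell being BAX (log2 -0.25) and BAK1 (log2 -0.46) in the authors' deposited table. With JQ1 3 of the 11 rose and 2 fell (3 and 3 adjusted over the list alone), and with BYL719 3 of 9 rose and 1 fell (3 and 2 adjusted over the list alone). The pro-apoptotic list was not called in cameraPR with any treatment, and its median (-0.18 with the combination) and its test differed in sign. The interferon list also had a negative median and a positive test with JQ1 and the combination. Of 14 death receptor and caspase genes, 3 rose and 3 fell with the combination (3 and 3 adjusted over the list alone, 2 and 4 when scaled to total counts). CASP8, the initiator caspase gene of death receptors, fell 2.69-fold and BIRC3 fell 5.77-fold in the authors' deposited table. The median of this list, 0.03 with the combination, became -0.19 when scaled to total counts.

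**Figure D2:**
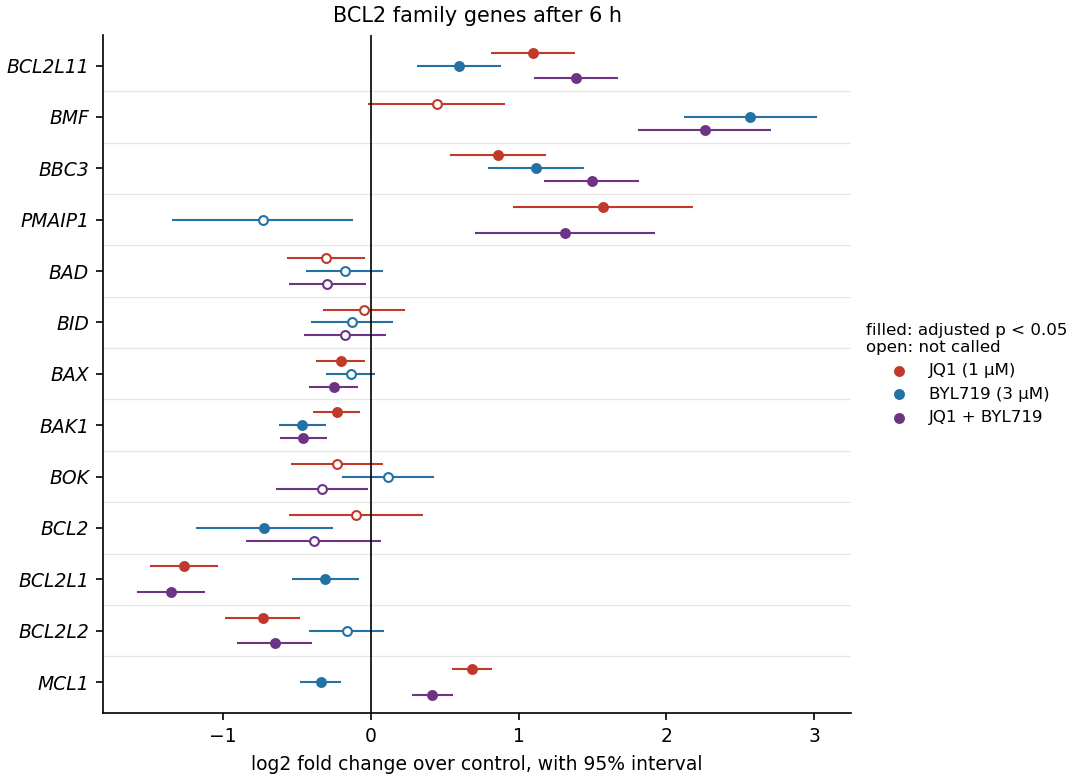
Log2 fold changes of 13 BCL2 family genes over control after 6 h in the authors' deposited tables (points) with 95% intervals (lines), for JQ1, BYL719 and the combination. Filled points passed an adjusted p of 0.05 and open points did not; BMF stood at 2.57 with BYL719 and 2.26 with the combination, and BCL2L1 at -1.26 with JQ1 and -1.35 with the combination.

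With the combination 19 of 22 FOXO targets rose and 1 fell (20 and 1 adjusted over the list alone, 17 and 1 when scaled to total counts), with a median log2 change of 0.98 and a cameraPR adjusted p of 3.86e-21. The member that fell was the receptor gene ERBB3 (1.31-fold lower in the authors' deposited table), and CCNG2 rose 5.30-fold and FBXO32 5.14-fold. Of 16 CDK inhibitors and p53 targets, 13 rose and 1 fell (14 and 1 adjusted over the list alone, 13 and 2 when scaled to total counts), with CDKN2B up 4.70-fold, TP53INP1 4.38-fold and CDKN1A 3.56-fold in the authors' deposited table (cameraPR adjusted p = 1.98e-17). Of 10 BET inhibitor-induced genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone, 8 and 0 when scaled to total counts; cameraPR adjusted p = 5.38e-07). Of 22 G1/S genes, 12 fell and 4 rose (12 and 4 adjusted over the list alone, 16 and 1 when scaled to total counts), and the cameraPR adjusted p of 0.00488 became an adjusted p of 0.0575 with the correlation of 0.05. Of 24 genes of the MYC list, 11 fell and 3 rose (11 and 3 adjusted over the list alone, 15 and 0 when scaled to total counts), with RRS1 down 3.19-fold and the RNA polymerase I subunit gene POLR1B 2.32-fold in the authors' deposited table. That list's adjusted p of 0.00568 became an adjusted p of 0.0644 with the correlation of 0.05. Of 17 glycolysis genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with an adjusted p of 0.0137 that became an adjusted p of 0.0719 with that correlation. Scaled to total counts, 4 glycolysis genes rose and 3 fell. Of 21 immediate early and ERK feedback genes, 10 fell and 4 rose (11 and 4 adjusted over the list alone, 13 and 4 when scaled to total counts), among them SPRY1 (4.01-fold lower) and SPRY4 (3.37-fold lower in the authors' deposited table). That list's adjusted p of 0.0173 became an adjusted p of 0.0972 with the correlation of 0.05. The calls of the first 3 lists held with it.

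The cholesterol list was not called with the combination: 3 of 20 rose and 4 fell (3 and 4 adjusted over the list alone), and 1 rose and 8 fell when scaled to total counts. SQLE, the squalene epoxidase gene, rose 1.58-fold with JQ1, fell 1.58-fold with BYL719 and stood at log2 0.17 (adjusted p = 0.156) with the combination in the authors' deposited tables.

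The remaining lists were not called with the combination. Of 23 genes linked to PAX3-FOXO1, 5 rose and 6 fell (5 and 6 adjusted over the list alone, 4 and 9 when scaled to total counts), with MYOD1 up 2.08-fold and MYOG down 2.96-fold, the receptor gene FGFR4 at log2 0.16 (adjusted p = 0.436) and FOXO1 at 0.12 (adjusted p = 0.274) in the authors' deposited table, and the median of 0.01 became -0.21 when scaled to total counts. Of 22 muscle differentiation genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, 1 and 5 when scaled to total counts), with DES, an intermediate filament gene of muscle, up 1.29-fold in the authors' deposited table, and the median of 0.09 became -0.13 when scaled to total counts. Of 27 PI3K pathway and receptor genes, 10 rose and 5 fell (11 and 6 adjusted over the list alone, 6 and 7 when scaled to total counts), with PIK3CA up 1.99-fold and IRS2 up 1.88-fold in the authors' deposited table, and the median of 0.11 became -0.11 when scaled to total counts. Of 11 BET proteins and partners, 6 rose and 3 fell (6 and 3 adjusted over the list alone, 5 and 5 when scaled to total counts), with BRD2 up 2.11-fold in the authors' deposited table. Of 20 ATF4 genes, 7 rose and 4 fell (8 and 5 adjusted over the list alone, 5 and 8 when scaled to total counts), with a median of 0.04 that became -0.18 when scaled to total counts. Of 18 G2/M genes, 5 rose and 7 fell (7 and 7 adjusted over the list alone, 0 and 8 when scaled to total counts), with a median of 0.08 that became -0.14 when scaled to total counts. Of 19 interferon-stimulated genes, 3 rose and 4 fell (4 and 4 adjusted over the list alone, 2 and 5 when scaled to total counts), with IRF7 up 5.05-fold and USP18 down 2.77-fold in the authors' deposited table. Of 4 anti-apoptotic BCL2 family genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 3 when scaled to total counts). Of 9 fatty acid synthesis genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone, 5 and 0 when scaled to total counts). Markers of other cell types gave no called list: 0 of 2 epithelial genes tested changed, CD34 fell among 5 blood cell markers (9.13-fold lower in the authors' deposited table), and PDGFRB fell among 11 fibroblast and matrix genes (1.54-fold lower). The fibroblast list's median of 0.15 became -0.07 when scaled to total counts. None of the 13 mitochondrially encoded genes of the last list was among the genes of the tables.

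**Figure D3:**
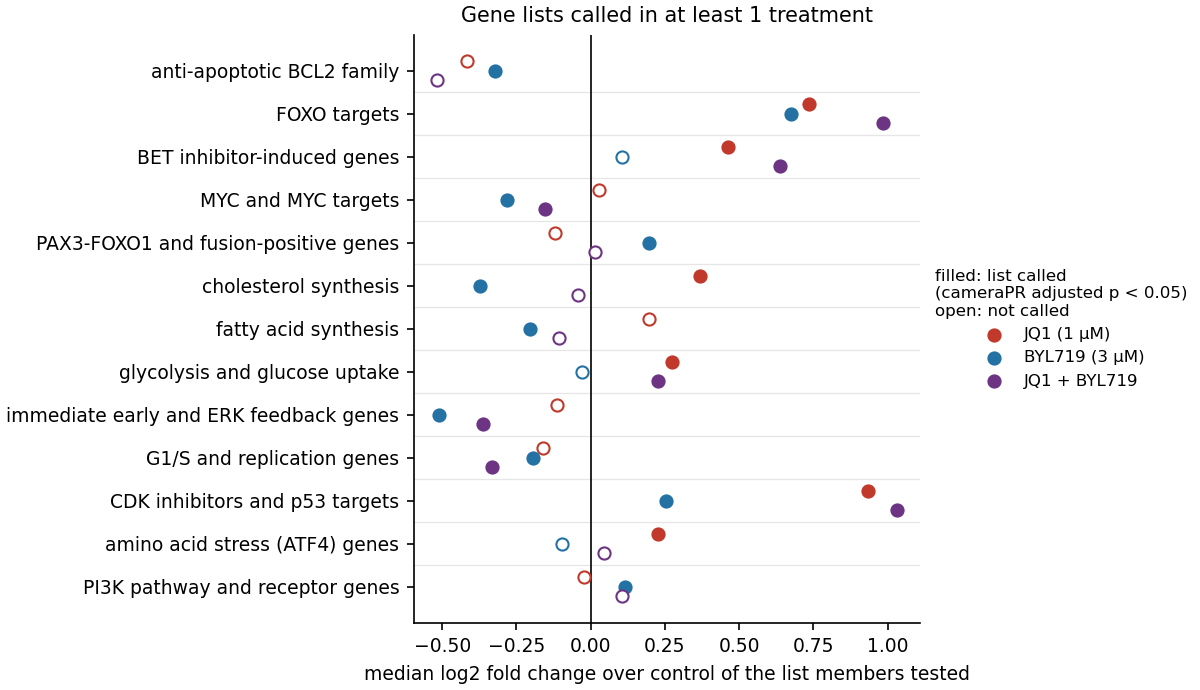
Median log2 fold change over control after 6 h of the members tested of each gene list called with at least 1 treatment, from the authors' deposited tables. Filled points mark lists called by cameraPR at an adjusted p under 0.05; FOXO targets stood at 0.73 with JQ1, 0.68 with BYL719 and 0.98 with the combination; when scaled to total counts the medians shift by 0.102, 0.0129 and 0.219 down, which turns the MYC list with JQ1 and the PAX3-FOXO1, ATF4 and PI3K lists with the combination to below 0.

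In total, 8380 of 23620 genes passed an adjusted p of 0.05 with the combination in the authors' deposited table, of which 4084 rose and 4296 fell (2201 and 6765 when scaled to total counts). Of these, 2131 changed by an absolute log2 of at least 1.

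The comparison of the combination with JQ1 asked what PI3K alpha inhibition added to BET inhibition. BMF stood 3.52-fold higher (log2 1.81, SE 0.330, adjusted p = 4.58e-05) and the FOXO target KLHL24 3.36-fold higher (SE 0.275). ABTB1, CREBRF and SMIM14 were the other largest rises, between log2 1.69 for SMIM14 and 1.83 for ABTB1. FOSL1 stood 2.59-fold lower (log2 -1.37, SE 0.280) and SPRY4 2.82-fold lower. METTL7B and the pseudogenes HSPA8P9 and HSPA8P8, whose reads can be shared with HSPA8, completed the 5 largest falls. IDI1 stood lower by log2 -0.60 (SE 0.147, adjusted p = 0.0101) and the fatty acid synthase gene FASN by log2 -0.63. Of 20 cholesterol genes, 4 fell and 0 rose (8 and 0 adjusted over the list alone), and of 22 FOXO targets 2 rose and 0 fell (7 and 0 adjusted over the list alone). Of 21 immediate early and ERK feedback genes, 3 fell and 0 rose (8 and 0 adjusted over the list alone, 5 and 0 when scaled to total counts). Of 24 MYC list genes 1 fell, RRS1 at log2 -0.82 (3 adjusted over the list alone, 5 when scaled to total counts). By cameraPR, FOXO targets stood above the other genes (adjusted p = 2.39e-17), and cholesterol synthesis (1.34e-14), immediate early and ERK feedback (1.55e-10), MYC (2.64e-06), fatty acid synthesis (6.48e-05), G1/S (0.000586) and ATF4 genes (0.00175) stood below. All 7 calls held with the correlation of 0.05. With the error that ignores the shared controls, few single genes passed in some lists: 1 of 9 fatty acid synthesis genes, 1 of 22 G1/S genes and 0 of 20 ATF4 genes fell. These counts were 4, 4 and 0 adjusted over the list alone and 4, 4 and 1 when scaled to total counts. With the per-gene error, which the list test used, they were 4, 5 and 2. By that error 11 FOXO targets stood higher, and 9 cholesterol, 9 immediate early and ERK feedback and 6 MYC list genes stood lower.

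Each difference was taken between 2 log2 fold changes, with an SE that ignores the shared control libraries and so overstates the error. On this basis 161 of 23620 genes passed an adjusted p of 0.05, 92 higher and 69 lower (57 and 437 when scaled to total counts). With the shared control part computed per gene, a choice made after the data were seen, 1148 genes passed, 518 higher and 630 lower. By that error BBC3 also stood higher than with JQ1 (log2 0.63, adjusted p = 0.00303 against 0.307) and MCL1 lower (log2 -0.27, adjusted p = 0.00555 against 0.309).

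The comparison of the combination with BYL719 asked what BET inhibition added to PI3K alpha inhibition. TEX14 (log2 4.15, SE 0.302), SESN3 (log2 3.04), SMIM14 (log2 3.02), HEXIM1 (log2 2.89, SE 0.216) and SERTAD1 (log2 2.66, SE 0.201) stood highest above BYL719. SH2D7 (log2 -4.27, SE 0.368), LINC00840, the myogenic factor gene MYF5 (log2 -3.30, SE 0.265), HAS2 and LINC01915 stood lowest. PMAIP1 stood higher by log2 2.04 (SE 0.441, adjusted p = 3.53e-05), MCL1 by 0.75 and BCL2L11 by 0.79, and BCL2L1 lower by log2 -1.04 (SE 0.164, adjusted p = 5.45e-09). Of 16 CDK inhibitors and p53 targets, 12 rose and 1 fell (12 and 1 adjusted over the list alone; cameraPR adjusted p = 8.47e-08), with CDKN2B higher by log2 1.72. Of 9 BET inhibitor-induced genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 0.000490), and of 21 FOXO targets 10 rose and 1 fell (10 and 3 adjusted over the list alone, 8 and 4 when scaled to total counts; adjusted p = 0.00129). After scaling to total counts, 8 CDK inhibitors and p53 targets rose and 1 fell, and 4 BET inhibitor-induced genes rose and 0 fell. Some FOXO targets had lower derived group means with the combination than with BYL719. These means were 87.85 against 155.4 normalized counts for PIK3IP1, 2791 against 3945 for IGF1R and 533 against 672.7 for INSR. Of 17 glycolysis genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, 2 and 0 when scaled to total counts). The glycolysis list's cameraPR adjusted p of 0.0282 became an adjusted p of 0.131 with the correlation of 0.05, while the other 3 calls held. Of 19 cholesterol genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), and the list's median of 0.18 became -0.03 when scaled to total counts. DES stood higher by log2 0.20 (adjusted p = 0.0448), and at log2 -0.01 (adjusted p = 0.940) when scaled to total counts.

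By the error that ignores the shared controls, 4708 of 13897 genes differed between the combination and BYL719, 2329 higher and 2379 lower (1107 and 4183 when scaled to total counts). With the shared control part computed per gene, 7098 differed, 3679 higher and 3419 lower.

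The interaction asked whether the combined change departed from the sum of the single changes on the log2 scale. WNT9A, a signalling ligand gene, was the 1 gene of 13897 past an adjusted p of 0.05 (interaction log2 -0.88, SE 0.174, adjusted p = 0.00536), and 363 genes had an unadjusted p under 0.05. WNT9A rose 4.25-fold with JQ1, 2.17-fold with BYL719 and 4.99-fold with the combination in the authors' deposited tables. Derived from these folds, its group means were 746 normalized counts in control, 3173 with JQ1, 1615 with BYL719 and 3723 with the combination. With the shared control part computed per gene 6 genes passed, each below the sum, among them WNT9A, SLFN5 (-0.68), the autophagy kinase gene ULK1 (-0.62), and RFPL4A and RFPL4AL1, near-identical paralogs whose reads cannot be separated with certainty. Among BCL2 family genes BMF stood at -0.75 (SE 0.402, adjusted p = 1.00) and BCL2L11 at -0.31 (SE 0.251, adjusted p = 1.00), so a departure from the sum was not detectable at this precision. FOXO targets stood below the sum as a list (median -0.31, adjusted p = 1.34e-05), as did CDK inhibitors and p53 targets (median -0.20, adjusted p = 0.000582), with 0 of their members called by the test of single genes, which called 1 gene in all. Both list calls held with the correlation of 0.05. The lists share SESN1, CDKN1B and GADD45A, so these calls are not independent. Genes linked to PAX3-FOXO1 (median -0.12), PI3K pathway genes (median -0.12) and fibroblast genes (median -0.16) also stood below the sum and the MYC list above it (median 0.12), but with that correlation their adjusted p became 0.0898, 0.132, 0.115 and 0.132. In simulated data with a true departure of 1.00 on the log2 scale, the test found 72.0% of 200 changed genes, and at 0.5 it found 9.5%. These simulations took the dispersion of each gene as known.

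**Figure D4:**
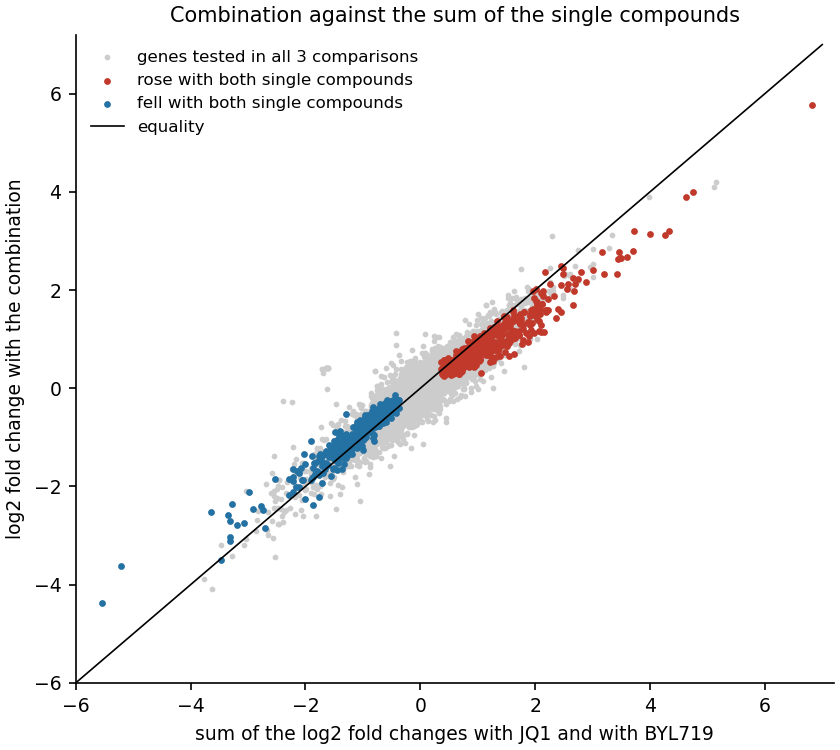
Log2 fold change with the combination (vertical) against the sum of the log2 fold changes with JQ1 and with BYL719 (horizontal) for 13897 genes (grey points), with genes that rose with both single compounds in red (464) and that fell with both in blue (544), from the authors' deposited tables. The line marks equality; the red genes had a median interaction of -0.222 and the blue genes of 0.158 (-0.326 and 0.054 when scaled to total counts).

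Of 13897 genes tested with both single compounds, 464 rose with both, against 275 for independent lists, 544 fell with both, against 358, and 598 changed in opposite directions. No value for independent lists was computed for the 598, so that count alone is no sign of opposed action. SMIM14, KLHL24 and CCNG2 were among those that rose with both, and RRS1, POLR1B and FOSL1 among those that fell with both in the authors' deposited tables. The log2 changes with JQ1 and BYL719 had a Pearson correlation of 0.149 across 12266 genes, which are not independent replicates. With no true effect, sharing the control libraries alone gave a simulated correlation of 0.5. The covariance was 0.0216 against a simulated 0.00913, an excess of 0.0125, and part of the excess overlap may come from the shared controls, which could not be split. JQ1 and the combination correlated at 0.917 and BYL719 and the combination at 0.411 across the same genes, with excess covariances of 0.270 and 0.0549.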

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

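The test of 1 scaling factor of the combination libraries was chosen only after the result was seen. The change with JQ1 in the presence of BYL719 differed from that in its absence for WNT9A (-0.88 on the log2 scale) and, by the cameraPR list test of limma, for 6 lists. Their median differences were -0.31 for FOXO targets, -0.20 for CDK inhibitors and p53 targets, -0.12 for genes linked to PAX3-FOXO1, 0.12 for MYC and its targets, -0.115 for PI3K pathway and receptor genes and -0.164 for fibroblast and matrix genes. With the correlation of 0.05 the last 4 of these lists lost their calls (adjusted p = 0.0898, 0.132, 0.132 and 0.115), and the first 2 kept theirs. A difference between groups drew attention to each of them.

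Genes that rose with both single compounds, such as WNT9A, ULK1 and SLFN5, rose less with the combination than the sum of the log2 changes. Their median interaction was -0.222 over 464 genes, against a simulated median of -0.0955 and a lowest simulated value of -0.115 in 100 additive simulations with shared controls and selection, so these account for part of the departure at most. The 544 genes that fell with both had a median of 0.158 against a simulated 0.0852 and a highest of 0.105. Scaled to total counts, however, the 2 medians become -0.326 and 0.054, the latter below the lowest simulated 0.0647. The departure of the genes that fell thus depends on the scaling. Most of the combination's shift in that scaling rests on the 20 most abundant genes (0.219 with them, 0.0924 without). An interaction moves by the combination's shift less those of JQ1 and BYL719. The latter were 0.102 and 0.0129 with these genes and 0.0816 and -0.0171 without, so both medians would move less without them. The medians were not recomputed without those genes. To reach the simulated range the genes that rose would need a shift of at least 0.107 and those that fell a shift of -0.0531 or lower, so 1 scaling factor would not bring both there. The departure of the genes that rose may reflect a limit to the change of genes on which both compounds act, but the genes are not independent and no test of such a limit was made.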

How the results depend on the processing

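Most values of named genes and most list tests kept their direction and their side of the threshold. Many named genes were picked for their large changes, so for them this was partly set in advance. Over all genes, scaling to total count moved the combination from 4084 higher and 4296 lower to 2201 and 6765. The list tests were not rerun with that scaling. Of 374 values of named genes against control, 180 were weaker at an absolute log2 of at least 1, which removes smaller changes by construction, 28 at an adjusted p under 0.01, 12 without a filter, 8 when scaled to total count and 5 at a mean of at least 10. None reversed. Requiring a log2 of at least 1 left 1813 genes with JQ1, 106 with BYL719, 2131 with the combination, 28 for the combination against JQ1, 1021 against BYL719 and 0 for the interaction (363 at an unadjusted p under 0.05 in the main DESeq2-based test). At an adjusted p under 0.01, 1642 genes remained with BYL719, 93 for the combination against JQ1 and 550 shared by JQ1 and BYL719. A smaller error raised the counts by construction: with the smaller of 2 preset shared parts of the squared error, 567 genes differed between the combination and JQ1 and 4 in the interaction; with the larger part 1198, 7093 against BYL719 and 5; with the shared part computed per gene 1148, 7098 and 6. Scaled to total count, 494 genes differed between the combination and JQ1 and 4 in the interaction. Of 158 values of differences 1 reversed: the value of DES, combination vs BYL719, went from 0.20 to -0.01046 (adjusted p = 0.940) when scaled to total count, and the cause is the shift of all genes in that scaling. Of 62 list tests against control 23 were called, 17 with the correlation of 0.05, 21 on ranks and 22 against protein-coding genes. With the combination, the MYC list and the immediate early and ERK feedback list lost their calls on ranks (adjusted p = 0.0941 for both in cameraPR), and the latter also against protein-coding genes (adjusted p = 0.0927). Of 61 list tests of differences 17 were called, and 5 calls were lost with the correlation of 0.05. With genes of a mean of at least 10 as background the fibroblast list lost its call in the interaction (adjusted p = 0.0734) and the cholesterol list was called for the combination against BYL719 (adjusted p = 0.0260), and on ranks the anti-apoptotic list was called in the interaction (adjusted p = 0.0476). No paired analysis was possible because the tables hold no value per library. For the same reason removal of single replicates, refits with DESeq2 or edgeR, other normalizations such as TMM, pseudocounts, fits of 6 samples, an estimated correlation, other splits of samples and a split of the controls were not run. The effect of depth was not tested; the authors' filter left genes with a mean from 2.11 with JQ1 and from 42.9 with BYL719.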

Other observations

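Of the heat shock genes, HSPA8 and DNAJB1 changed in opposite directions with the single compounds. The gene families of this part were chosen after the values were seen. In the authors' deposited tables HSPA8 rose with JQ1 (log2 0.62) and fell with BYL719 (log2 -1.16) and the combination (log2 -0.54), and the co-chaperone gene DNAJB1 rose with JQ1 (log2 0.64), fell with BYL719 (log2 -0.64) and stood at 0.00 with the combination. Of 30 heat shock genes 14 rose and 3 fell with JQ1, and 1 rose and 15 fell with BYL719 (cameraPR adjusted p = 1.47e-07). The call with JQ1, an adjusted p of 0.0140, became an adjusted p of 0.136 with the correlation of 0.05. HSPA5, a chaperone gene of the endoplasmic reticulum, rose with JQ1 (log2 1.11) and the combination (log2 0.80) in the authors' deposited tables. Of 30 histone genes 24 rose with JQ1 and 28 with the combination, with medians of 0.46 and 0.62 (0.36 and 0.40 when scaled to total counts), among them H3-3B (log2 0.98 with JQ1 in the authors' deposited table). Of 79 ribosomal protein genes 63 rose and 4 fell with the combination, with a median of 0.35 that became 0.13 when scaled to total counts.

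The test of small non-coding RNAs was chosen only after the result was seen. Ribosomal protein genes stood higher with the combination than with JQ1 by a median of 0.22, which became 0.10 when scaled to total counts, and 27 of 79 passed with the per-gene error. RPS3 stood at log2 0.25 (adjusted p = 0.405 with the shared controls ignored and 0.0129 with the per-gene error). If more short RNA in the combination libraries were the cause, other short protein-coding transcripts would stand higher as well. The shortest of these, 1044 genes with transcripts up to 611 nt, stood 0.0188 higher than the rest (95% interval 0.00354 to 0.0355). That is far less than the 0.22 of the ribosomal protein genes. Length was the median over the annotated transcripts of a gene, which can differ from the length of the transcript expressed. The test therefore cannot exclude more short RNA as the cause. Genes with transcripts under 200 nt stood 0.342 higher, of which 61.2% were small RNAs, among them SNORA71A (log2 0.76, adjusted p = 0.405 with the shared controls ignored and 0.0120 with the per-gene error), and the other 26 of them stood 0.182 higher. The median was 0.107 for transcripts of 200 to 400 nt, 0.0116 for 400 to 700 nt and -0.0372 above 2000 nt, so it declined with length over all genes. This could come from RNA size selection or from a change in these RNAs, and the test cannot tell them apart.

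Processed pseudogenes followed their parent genes. Over 721 pairs the log2 fold changes with the combination correlated at 0.847, against a highest value of 0.119 in 1000 re-pairings, across genes that are not independent. Shared reads are a likely source, and values of pseudogenes such as HSPA8P9 may therefore be those of the parent.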
